A study of Danio rerio with 2 samples.

How the data were processed

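Genomic DNA from hearts dissected from zebrafish embryos at 48 hours post fertilisation was profiled by enhanced reduced representation bisulfite sequencing. In this assay DNA is cut with a restriction enzyme that enriches for CpG-rich fragments and is then treated with bisulfite, which converts unmethylated cytosine to uracil (read as T) and leaves 5-methylcytosine and 5-hydroxymethylcytosine to be read as C, so the assay does not separate these forms. There were 2 libraries, 1 from wild-type hearts and 1 from hearts of double mutants with inactivating mutations in tet2 and tet3, which encode enzymes that oxidise 5-methylcytosine. Per the labels, both libraries have AB as background, and the wild-type fish descend from AB and TU parents; the parents of the double mutants are not given in the sources used here. With 1 library per genotype no value has a replicate error, and every test below compares the reads of these 2 libraries, not the genotypes.

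The deposited tables list, for each CpG cytosine on each strand, the coverage as a raw read count of at least 1 and the percent of those reads carrying C or T, per the file headers. Genome build danRer10 and CASAVA 1.8.2 are named in the submitters' processing notes; the aligner, the methylation caller and any removal of duplicate reads are not given in the sources used here. Multiplying the deposited percent of C by the count gave a whole number of reads, within 0.02, at 99.9994% of wild-type and 99.9976% of double-mutant positions, so methylated and unmethylated read counts were recovered by rounding. Reads carrying another base were left out of the levels. Both libraries covered 25 chromosomes and the mitochondrial genome.

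The wild-type library held 6523061 nuclear strand positions with a median of 5 reads, and the double-mutant library 1815799 positions with a median of 29 reads. The 2 strand positions of a CpG were summed. Comparisons used CpGs with at least 10 reads in both libraries, without the 0.1% of deepest CpGs in either. The level of a CpG is its percent of methylated reads. Mean levels and their differences carry 95% percentile intervals from a bootstrap of 1 Mb blocks of the genome (1000 draws), which cover the spread over the genome and counting error only, not the variation between fish.

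Single CpGs were tested with a two-sided Fisher's exact test on methylated and unmethylated reads, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a difference of at least 25 percentage points. Fixed tiles of 1 kb with at least 3 CpGs were tested in the same way on summed reads, and called at an adjusted p under 0.05, a difference of mean CpG levels of at least 20 points and at least 75% of CpGs moving the same way. To measure the background of these calls, the reverse strand was tested against the forward strand of the same CpGs within each library. For differences by wild-type level, the wild-type forward strand set the class, in steps of 20 points, and the reverse strand gave the values. This keeps regression to the mean out of the differences between the libraries, but not out of the levels, so the reverse-strand level of a class can lie outside its limits. Each strand position used had at least 10 reads. Methylated reads on the mitochondrial genome were taken as an estimate of unconverted cytosine, with exact Clopper-Pearson intervals. These designs, the alternatives and the rule for the tiles named (the 10 called tiles with the largest gain and the 10 with the largest loss, ties in chromosome order) were fixed before the data were examined. Promoters, genomic features and fixed lists of heart, blood, developmental and other marker genes, with tet2, tet3, inhbaa and sox9b, had also been planned and were not analysed here, because no annotation of danRer10 was used here; the gene table at hand is of assembly GRCz12tu, so regions are given by danRer10 position without gene names.

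Reads in these tables were not independent molecules, since strand positions with 10 to 19 reads were mostly fully methylated or fully unmethylated. After this was seen, the effective number of molecules behind a strand position was estimated for each depth class from the squared difference between the 2 strands of a CpG in 1 library, and called tiles were tested again on effective molecules. In each 100 bp and strand, the number of molecules was that of the deepest position and the level was the mean over positions, and a tile counted as called by molecules only if it was also called by reads. The number at a given depth is an average over the library, not measured in the tile. Numbers were summed over the 100 bp steps and strands of a tile as if independent. A fragment that crosses from a step into the next is thus counted more than once. In this molecule test an adjusted p is again from a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. Dense tiles of at least 15 CpGs, tiles called on each strand by itself, chromosomes, 100 kb windows with at least 50 CpGs and CpG density (covered CpGs within 250 bp on each side) were also added at that point.

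The calls were tested on simulated data with the positions and depths of the comparison of the double mutant with wild type, with 200 of 131614 tiles changed. With independent reads, 94.0% of tiles raised by 50 points and 67.0% of tiles raised by 30 points were recovered, and 4 unchanged tiles were called (1 higher and 3 lower). With reads drawn as copies of few molecules, 59.0% and 45.0% were recovered, 5804 unchanged tiles were called higher and 4784 lower, and 20.1% of unchanged CpGs were called, while the mean difference of unchanged CpGs was 0.018 points, near 0 by construction. The same simulation gave class shares and shares of moved tiles with both libraries drawn at the pooled level of their reads at each CpG. That pooled level itself rests on few molecules, so these are not the exact shares expected with no difference. The molecule test called 0 unchanged tiles in either simulation. It recovered 1.0% of tiles raised by 50 points and 0% of those raised by 30 points, so it missed most of the simulated changes. Only 200 tiles were changed, and the Benjamini-Hochberg limit is stricter when fewer tiles differ. These shares therefore need not hold in the data. The simulation of copies drew molecules independently in each 100 bp and strand, as the molecule test assumes, so it cannot check that assumption. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.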

Results

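DNA methylation was compared between hearts of wild-type zebrafish embryos and hearts of tet2/3 double mutants at 48 hours post fertilisation, with 1 bisulfite library per genotype. The comparison asks how CpG methylation in the heart differs when the Tet2 and Tet3 enzymes, which oxidise 5-methylcytosine as a step of demethylation, are inactivated. The wild-type library held 90041851 nuclear CpG observations (a read counted once at each CpG it covers) on 5630778 CpGs, and the double-mutant library 97804408 on 1620498 CpGs. At least 10 reads were reached at 28.8% of wild-type CpGs and 82.4% of double-mutant CpGs. There were no replicates, so no value has an error between fish. Neither the coding sequence nor the activity of tet2 and tet3 is read by this assay, so the genotypes rest on the labels.

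CpG methylation was higher in the double-mutant library. Over the 956410 CpGs with sufficient reads in both libraries, the mean level was 70.8% in wild type (95% block bootstrap interval 70.4 to 71.2%) and 80.2% in the double mutant (79.8 to 80.6%). The difference was 9.44 points (9.28 to 9.60). Median depth at these CpGs was 46 reads in wild type and 68 reads in the double mutant. All 25 chromosomes had a higher level in the double mutant, with an interval above 0 on each, and the differences ran from 8.59 points on chromosome 3 to 10.2 points on chromosome 13. Of 9128 windows of 100 kb, 98.4% were higher in the double mutant, with a median difference of 8.78 points.

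Fewer CpGs had intermediate levels in the double-mutant library and more were at 90% or more. CpGs at 90% or more made up 33.8% of shared CpGs in wild type and 67.0% in the double mutant. CpGs strictly between 10% and 90% made up 53.9% in wild type and 19.5% in the double mutant. CpGs at 10% or less made up 12.3% in wild type and 13.5% in the double mutant, and 91.5% of those in wild type were also at 10% or less in the double mutant. The sizes of these classes also depend on the number of molecules sampled per position, which was lower in the double-mutant library. In a simulation of that effect, with both libraries drawn at their pooled level of each CpG, 52.8% of wild-type and 64.2% of double-mutant CpGs were at 90% or more, 34.6% and 19.6% lay between 10% and 90%, and 12.6% and 16.2% were at 10% or less.

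**Figure D1:**
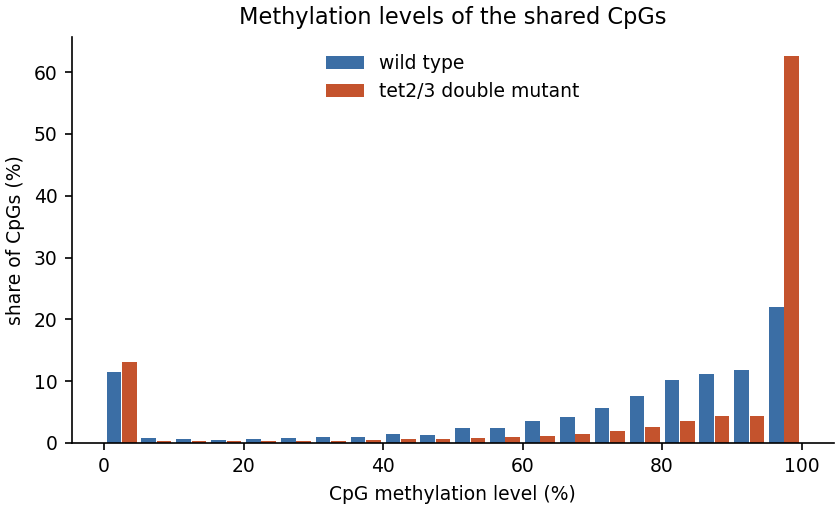
Share of the 956410 shared CpGs (vertical axis, percent) by methylation level in steps of 5 points (horizontal axis, percent) for the wild-type and double-mutant libraries. Wild-type CpGs spread over the upper levels, with 33.8% at 90% or more, whereas 67.0% of double-mutant CpGs lie there.

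Read depth overstated the number of molecules in both libraries, more so in the double mutant. Strand positions with 10 to 19 reads were fully methylated or fully unmethylated at 53.8% in wild type and at 95.6% in the double mutant. From the disagreement of the strands of the same CpG, positions with 40 to 79 reads held an estimated 5.56 effective molecules in wild type and 1.95 in the double mutant. Binomial and Fisher tests on read counts take these copies as independent, so they understate even the counting error. Single-CpG values of the double mutant carry little information each.

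Of the shared CpGs, 174175 were called higher and 44260 lower in the double mutant (Fisher's exact test, adjusted p under 0.05 and at least 25 points). Called-higher CpGs averaged 53.9% in wild type and 97.3% in the double mutant, and called-lower CpGs averaged 83.7% and 32.2%. These were 18.2% and 4.63% of the shared CpGs. In the simulation of copies of few molecules, 192405 unchanged CpGs were called, or 20.1%. A call at a single CpG is thus weak evidence of a change there. The strand comparison gives a background by direction, on fewer CpGs. Over the 113535 CpGs with at least 10 reads on each strand of each library, the reverse strand was called higher than the forward strand at 8474 CpGs and lower at 8316 within wild type, and higher at 8218 and lower at 8347 within the double mutant. On the same CpGs the double mutant was called higher than wild type at 18452 forward positions and lower at 3748. The count of lower calls was thus below that of either strand comparison, and the count of higher calls was above both.

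Classes of intermediate level on the wild-type forward strand differed most in points. CpGs at 20 to 40% on the wild-type forward strand averaged 61.0% on the wild-type reverse strand and 82.7% on the double-mutant reverse strand, a difference of 21.7 points (20.5 to 22.7, 5267 CpGs). CpGs at 40 to 60% differed by 16.8 points (16.2 to 17.5), those at 60 to 80% by 11.5 points (11.1 to 11.8), and those at 80 to 100% by 8.35 points (8.15 to 8.54). On the wild-type reverse strand these 3 classes averaged 72.2%, 79.2% and 82.7%, so each had less room to gain than the class below it. How far this sets the order of the differences was not tested. In the lowest class, at 0 to 20%, the level was 10.8% in wild type and 14.4% in the double mutant, a difference of 3.59 points (3.31 to 3.89, 27368 CpGs). In that class 83.3% of CpGs were at 10% or less on the wild-type reverse strand and 82.0% on the double-mutant reverse strand, while 3.93% and 10.9% were at 90% or more. These shares also depend on the molecules per position, which were fewer in the double-mutant library. They therefore do not count CpGs that became fully methylated.

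**Figure D2:**
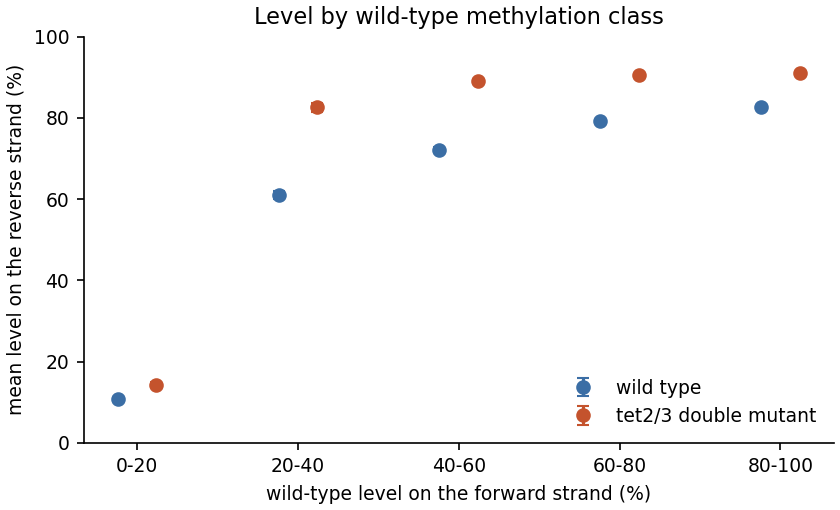
Mean reverse-strand CpG level (vertical axis, percent) in each library for classes of wild-type forward-strand level (horizontal axis, percent); bars are 95% block bootstrap intervals and are mostly smaller than the points. The libraries lie 21.7 points apart at 20 to 40% and 3.59 points apart at 0 to 20%.

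Regional gains far outnumbered regional losses. Of 131614 tiles of 1 kb with at least 3 shared CpGs, 23803 were called higher and 1262 lower in the double mutant, while 75.2% of all these tiles, called or not, had a higher level in the double mutant. Tiles called higher averaged 61.0% in wild type and 95.4% in the double mutant. On tiles with reads on both strands, the forward strand alone gave 2086 tiles higher and 124 lower and the reverse strand alone 2063 higher and 109 lower, of 13883 tiles. The same tile was called higher on each strand by itself in 798 cases and lower in 24 cases. These were 38.3% of the tiles called higher on the forward strand and 19.4% of those called lower there. Another 12 tiles were called higher on the forward and lower on the reverse strand, and 10 the other way. The tile differences on the 2 strands had a correlation of 0.436. Strand against strand within a library gave 700 and 683 calls in the 2 directions in wild type and 234 and 228 in the double mutant. Of the called tiles, 295 higher and 3 lower also passed the test on effective molecules.

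The tiles with the largest differences by read counts were short and rested on few molecules. The 10 tiles with the largest gain were all at 0% in wild type and 100% in the double mutant, over 3 to 5 CpGs within 13 to 49 bp, and the 10 with the largest loss were all at 100% in wild type and 0% in the double mutant, over 3 to 6 CpGs within 22 to 50 bp. An example of a gain is chromosome 3 from 58105001 to 58106000 (danRer10), with 156 wild-type and 119 double-mutant reads on 3 CpGs. An example of a loss is chromosome 20 from 8232001 to 8233000, with 90 and 96 reads on 6 CpGs. These gained tiles held an estimated 1 to 5 double-mutant molecules and the lost tiles 1 to 3, and 0 of the 20 passed the molecule test. With so few molecules that test could hardly pass even at 0% against 100%, so its outcome adds nothing to the molecule numbers.

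Dense tiles of at least 15 CpGs, selected after the data were seen, gave gains that rest on more molecules. Of 6575 such tiles, 334 were called higher and 10 lower by reads, and 33 higher and 0 lower also by effective molecules. The molecule test takes the 100 bp steps and strands of a tile as independent, so its molecule numbers can be too high and its p-values too small. The tile on chromosome 5 from 18792001 to 18793000 went from 18.9% in wild type to 89.7% in the double mutant over 23 CpGs, with an estimated 47 and 19 molecules (Fisher's exact test on molecules, adjusted p = 2.5e-05). The tile on chromosome 22 from 18548001 to 18549000 went from 24.2% to 93.4% over 18 CpGs (exact test on molecules, adjusted p = 0.0073). The tile on chromosome 7 from 15673001 to 15674000 went from 30.7% to 93.4% over 17 CpGs. The tile on chromosome 10 from 1001 to 2000, at the start of the assembled chromosome, went from 20.7% to 83.0% over 17 CpGs. A tile on chromosome 22 from 11141001 to 11142000 went from 38.0% to 99.3% over 28 CpGs, and a tile on chromosome 10 from 916001 to 917000 went from 32.6% to 93.3% over 20 CpGs. Among the 10 tiles with the largest gain of the dense tiles called by molecules, wild-type levels ran from 18.9 to 38.0%, double-mutant levels from 83.0 to 99.3%, and gains from 56.3 to 70.7 points. Whether these tiles lie in genes, promoters or repeats was not analysed here.

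**Figure D3:**
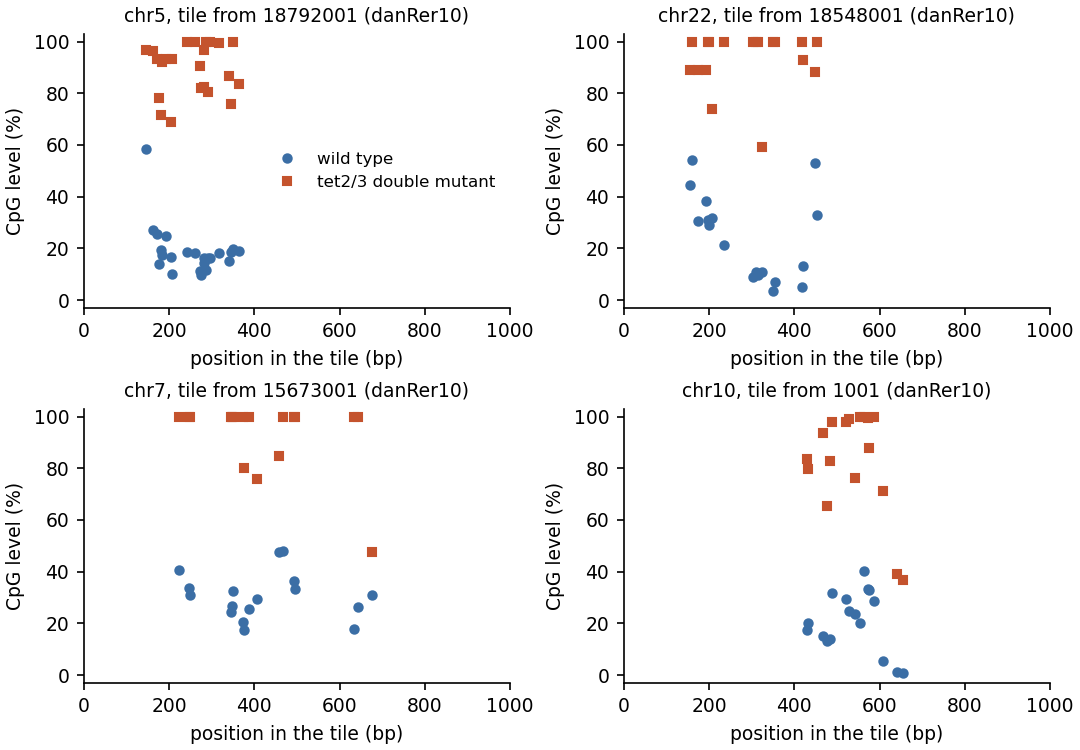
CpG methylation level (vertical axis, percent) of each shared CpG along 4 of the dense 1 kb tiles with the largest gain among those called by molecules (horizontal axis, bp from the tile start) in the wild-type library (circles) and the double-mutant library (squares). Double-mutant CpGs lie above wild-type CpGs through each tile, as on chromosome 5, with means of 18.9% and 89.7%.

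Along chromosome 4 the difference between the libraries varied. Its first 30 Mb averaged 66.3% in wild type and 78.0% in the double mutant, a difference of 11.7 points (10.03 to 13.4). Beyond 30 Mb it averaged 81.0% (79.7 to 82.0%) and 87.3% (86.0 to 88.3%), a difference of 6.31 points (5.82 to 6.79). The other chromosomes together averaged 70.7% and 80.1%, a difference of 9.46 points (9.30 to 9.63). The interval of the part beyond 30 Mb overlaps neither of the others. The limit at 30 Mb was chosen after the profile was seen and is not a sharp border of the difference. The segment at 0 to 5 Mb differed by 7.72 points (5.67 to 10.6), the segment at 25 to 30 Mb by 9.93 points (8.78 to 11.7) and the segment at 30 to 35 Mb by 8.69 points (7.19 to 10.5), and these intervals overlap.

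**Figure D4:**
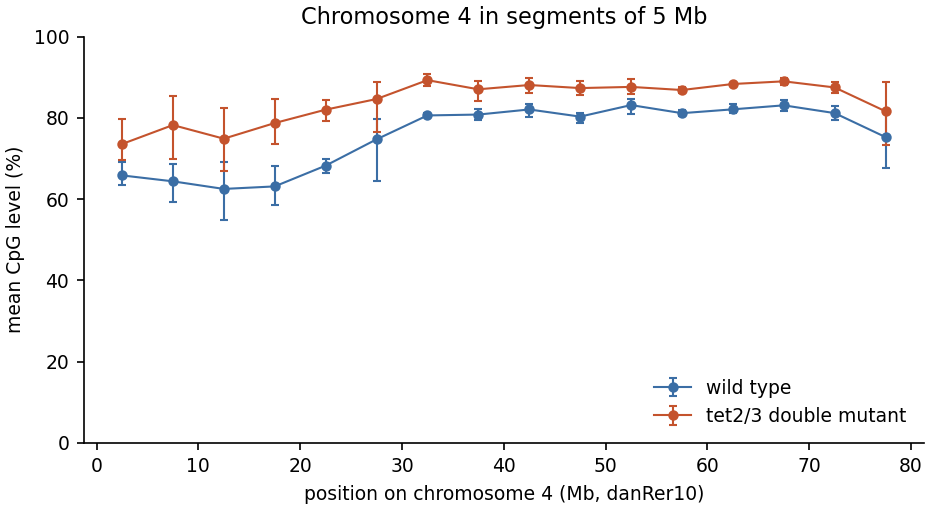
Mean CpG level (vertical axis, percent) along chromosome 4 in segments of 5 Mb (horizontal axis, Mb) in both libraries, with 95% bootstrap intervals over blocks of 1 Mb. The libraries lie 7.72 points apart at 0 to 5 Mb, 15.6 points apart at 15 to 20 Mb, 8.69 points apart at 30 to 35 Mb and 4.48 points apart at 50 to 55 Mb.

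Mitochondrial DNA, which gives an estimate of cytosines left unconverted by bisulfite, read as methylated at 0.247% in wild type (exact binomial interval 0.232 to 0.262%, 436335 observations) and 0.184% in the double mutant (0.172 to 0.197%, 462094 observations). These intervals take each observation as independent. Nuclear reads were copies of fewer molecules, so the mitochondrial intervals can be too narrow. The double-mutant share was lower by this measure, whereas the nuclear level of that library was higher by 9.44 points.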

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

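The 3 tests of the first pattern were chosen after its result was seen. The tests of the other patterns were set out after the patterns were seen and before the tested values were computed, but 2 of their decision rules were altered afterwards, as stated with each. Outside the main comparison, 0.0286% of double-mutant reads at CpG cytosines carried neither C nor T, against 0.0266% in the wild-type control. CpGs covered in the double-mutant library only, which entered none of the comparisons over shared CpGs, averaged 80.5%, against 74.7% for CpGs covered in the wild-type library only, which had a median of 4 reads.

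The first pattern is the higher level in the double-mutant library. Unconverted cytosine is argued against as the source by the mitochondrial share, which was lower in the double mutant (difference -0.063 points). Copies of few molecules in that library, drawn without a preference, are argued against as the sole source. Such copies leave the mean level where it was, and the mean differed by 9.44 points (9.28 to 9.60). Of the tiles that moved by 20 points or more 91.7% were higher on each strand, against 48.5% and 48.0% in a simulation of copies with no difference. That simulation fixes an even share in advance, so the share of higher tiles restates the mean difference and is no separate evidence. A loss of the same fraction of methylated signal everywhere in wild type is argued against as the sole source, since the ratio of wild-type to double-mutant mean level was 0.98 at the densest CpGs (41 or more within 250 bp) and 0.882 over all CpGs, a difference of 0.097 (block bootstrap interval 0.083 to 0.113). The inactivation of tet2 and tet3, a different make-up of the dissected tissue, parents and any step of library preparation that differed, such as unequal amplification of methylated and unmethylated copies or a loss that depends on CpG density, stay open, because each genotype has 1 library.

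The second pattern is the set of CpGs that lost at least 80 points on both strands. Only 3 CpGs did so, and of their 12 neighbours within 100 bp 16.7% also lost at least 50 points, as a sequence variant at the CpG would give, but 3 CpGs are too few to decide. The planned bound alone would have read this share in favour of a variant; a minimum of 10 CpGs was added after the value was seen. Gains of at least 80 points on both strands were found at 124 CpGs, and 83.2% of their 613 neighbours also gained at least 50 points, which copies of a single methylated molecule that spans them would also give.

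The third pattern is the smaller difference on chromosome 4 beyond 30 Mb. Collapsed copies of repeated sequence would raise the read depth there. The median depth was 0.83 times that of the other chromosomes in wild type and 0.794 times in the double mutant. This argues against a collapse at most of these CpGs only, since a median does not show one at a minority. Depth is also an indirect measure of genomic copies, because reads were copies of few molecules. A higher wild-type level that leaves less room to gain found no backing. It was tested on 2010 CpGs of this part with at least 10 reads on each strand used, against 19910 in the difference given above. Matching on the wild-type forward strand did not shrink the gap in reverse-strand gain to the other chromosomes. On these CpGs the gap was -2.35 points unmatched and -2.89 points matched (interval -3.89 to -1.57), past the planned bound against this explanation. The explanation is not excluded, because the match was incomplete, with the wild-type reverse strand still 2.00 points higher there (0.716 to 3.06). The interval of the matched gap also spans that bound of 2 points. The double-mutant level in the same matched sets differed by -0.881 points (-2.15 to 0.244), where less room to gain would give no lower level, and this interval includes 0. Leaving the explanation open was decided after the matched gap was seen, as were a change to the limit on its interval and the test on the double-mutant level.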

How the results depend on the processing

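The tests on effective molecules, on each strand by itself and on tiles of at least 15 CpGs were added after the data were seen. The difference in mean level stayed positive in every setting tried. It was 9.76 points with a minimum of 5 reads, 8.82 with a minimum of 20 reads, 9.07 with strand positions kept apart, 11.6 as a read-weighted mean and 12.02 over all CpGs of each library with at least 10 reads. With no upper limit on coverage (9.43) the difference stayed within its interval. Thinning to equal reads at each CpG gave 9.44, but random thinning leaves the expected level of a CpG unchanged, so it could not move the mean. It also did not make the numbers of molecules equal. Higher calls outnumbered lower calls in every setting that set the double mutant against wild type. CpG calls numbered 328818 higher and 69074 lower at 10 points, 81808 and 26151 at 40 points, and 28826 lower with a minimum of 20 reads (118986 higher). Tile calls numbered 11007 higher and 411 lower with at least 5 CpGs, 45120 and 2157 at 10 points, and 11858 and 722 at 30 points. Their number depends most on treating reads as molecules: also by effective molecules 295 tiles were higher and 3 lower, and with at least 15 CpGs 33 and 0, against 334 and 10 by reads on the same dense tiles. This molecule test recovered 1.0% of simulated tiles raised by 50 points, in a simulation with only 200 changed tiles. Its recovery in the data is not known, so its low counts do not bound the number of changed tiles. Called on each strand by itself, 798 tiles were higher and 24 lower. As backgrounds on fewer CpGs, the reverse strand against the forward strand gave 8474 CpGs higher and 8316 lower and 700 tiles higher and 683 lower in wild type, and 8218 and 8347 CpGs and 234 and 228 tiles in the double mutant. By wild-type level, with the reverse strand setting the class, the difference at 40 to 60% was 17.9 points. With a minimum of 20 reads per strand it was 2.59 points at 0 to 20%, 24.5 at 20 to 40%, 17.8 at 40 to 60% and 7.89 at 80 to 100%. The cause of these shifts between settings was not tested, apart from counts that follow from fewer or more CpGs passing a stricter or looser limit. The mitochondrial shares moved by less than their intervals. Alternatives planned for promoters, genomic features and gene lists gave no value, since no danRer10 annotation was used here. No replicate could be left out with 1 library per genotype. No paired analysis was possible because each genotype has 1 library.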

Other observations

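Over all wild-type levels together, sparse CpGs differed more than dense ones. CpGs with 1 to 5 covered CpGs within 250 bp on each side averaged 77.1% in wild type and 88.3% in the double mutant, a difference of 11.2 points (95% block bootstrap interval 11.02 to 11.4). With 21 to 40 CpGs in that span the levels were 49.6% and 53.8%, a difference of 4.18 points (3.96 to 4.40), and with 41 or more they were 29.4% and 30.01%, a difference of 0.608 points (0.153 to 1.11). Among CpGs at 20 to 60% on the wild-type forward strand, the reverse-strand difference was 14.9 points in the sparsest class, 18.2 points with 6 to 10 CpGs, 21.3 points with 11 to 20 CpGs, 13.1 points with 21 to 40 CpGs and 8.85 points with 41 or more, the last over 50 CpGs. The sparsest class was thus not the highest there. Wild-type reverse-strand levels of these sets were 73.9%, 70.2%, 65.5%, 66.0% and 48.4%, so they also differed in the room left to gain. These groupings were chosen after the data were seen.

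At the scale of 100 kb, some windows of low level were low in both libraries. The window on chromosome 3 from 23500001 to 23600000 (danRer10) averaged 2.92% in wild type and 3.02% in the double mutant over 189 CpGs, and the window on chromosome 23 from 35900001 to 36000000 averaged 4.34% and 5.06% over 106 CpGs. The 117 windows under 30% in wild type had a median difference of 3.64 points. Of these, 1 differed by 20 points or more, on chromosome 10 from 10900001 to 11000000, from 29.04% to 62.8% over 89 CpGs. Differences of at least 20 points in the mean were found in 456 windows, all of them gains. The largest gain was on chromosome 5 from 15500001 to 15600000, from 47.6% to 93.4% over 65 CpGs, and a window with 231 CpGs on chromosome 22 from 11100001 to 11200000 went from 35.6% to 71.2%. The largest loss was on chromosome 23 from 31500001 to 31600000, from 61.2% to 42.1% over 53 CpGs, and the windows on both sides of it were also lower in the double mutant, by -8.01 points from 31400001 to 31500000 and by -7.38 points from 31600001 to 31700000. These windows were picked for their size after the data were seen and carry no test.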
